A study of Homo sapiens with 9 samples.

How the data were processed

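Total RNA of HEK293 cells was labelled with biotin and hybridised to Affymetrix HG-U133 Plus 2.0 arrays, per the labels. The deposited table held 1 column of log2 values per array for 54675 probe sets. The submitters' processing notes name MAS5, with no version. The scale is not stated there and was read from the values, which ran from about 4.5 to 14.6 on every array. The spread between arrays of a dose was small among the dimmest probe sets (median SD 0.0519 in the dimmest 10%, 0.0520 in the brightest 10%, up to 0.104 between), as model-based summaries give, so the summarization method behind the values is not settled. A fold change printed here is therefore a difference of deposited log2 values. Background correction, normalization between arrays and a genome build were not given in the sources used here. The test plan made before the data were examined expected linear MAS5 signals, to which a pseudocount would be added, and provided for log2 values to be used as deposited unless array medians differed by over 0.15. The latter case applied, so no pseudocount was added and the arrays were not scaled further.

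Each array's dose and batch number came from its title. The 10 mM array called batch 2 in its title is called batch 1 in its source name. The titles say that a number marks a batch, so the numbers pair the arrays by label. Deviations of same-numbered arrays from their dose means correlated between -0.0671 and 0.0416 over 9 pairs, and none exceeded 0.1. The main fit had no block, and fits with the batch number as a block were alternatives.

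The 62 control probe sets were set aside, and of the other 54613 the upper 50% by mean log2 value over all 9 arrays, 27307 probe sets, were tested. The platform annotation gave 41097 probe sets a single gene symbol, 1801 several and 11777 none, and 41043 of the single symbols were updated through their Entrez identifiers. Probe sets with several symbols were given no gene name. limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) was fitted to all 9 arrays with dose as a factor, which left 6 residual degrees of freedom, and the median residual SD was 0.0819. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. A linear trend used dose in mM as a number. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

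For each of the comparisons against 0 mM, the 12 genes that rose and the 12 that fell with the largest absolute log2 change were named, among probe sets with a single gene, an adjusted p below 0.05 and the same sign of difference in all 3 batches. For 10 against 5 mM, 5 in each direction were named. SIRT1, PARP1, NAMPT and NNMT were named whatever their result, as were 2 to 4 members of each described list with the smallest raw p at 10 mM. 2 transcripts picked by this rule are not reported here, so the genes named do not include every one of the largest changes. MDM2, CCN1 and COL1A1 were added after their values were seen, as members of described lists.

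Of 27 gene lists fixed before the data were examined, 26 had at least 5 members among the tested genes, each gene represented by its brightest kept probe set. They were tested with camera at an inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. No list passed with the estimated correlation at either dose, while fry, which asks whether a list's genes move on balance in a single direction, called 26 lists at 10 mM and 22 at 5 mM. RNA quality was read from log2 ratios of the 3' to the 5' control probe sets of ACTB and GAPDH with exact permutation tests, whose smallest p is 0.1 for 3 against 3 arrays. The correlation of changes at the 2 doses was set against 100 simulated draws of unchanged groups.

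The fits were tested on simulated data for 27307 probe sets with 200 changed. For 10 against 0 mM, 40.3% of changes of 1.2-fold, 98.5% of 1.5-fold and 100% of 2-fold were recovered, with 9 false calls. For 5 against 0 mM the shares were 23.9%, 97.0% and 100% with 8 false calls, for 10 against 5 mM 26.9%, 94.0% and 100% with 5, and for the dose trend 34.3%, 91.0% and 100% with 4. In a simulation of the list test for 10 against 0 mM over 13060 genes, all 5 shifted lists were found and 0 others were called. Both simulations drew independent noise for each probe set or gene and left all others unchanged. They therefore do not measure false calls where genes are correlated or where most probe sets change, as in these data. The simulated trends were straight lines, so the shares recovered for the trend do not hold where 5 mM departs from a line. The gene XPOT, for example, changed by -1.80 at 10 mM and 0.86 at 5 mM, and its trend did not pass (limma adjusted p = 0.139). Alternatives covered the batch block, normalization, the filter on dim probe sets, the variance model, the arrays in the fit, a fold threshold, and each array or batch left out.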

Results

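The series profiled HEK293, an established human embryonic kidney cell line, 24 hours after addition of isonicotinamide at 0, 5 or 10 mM. Isonicotinamide is an isomer of nicotinamide, the amide form of vitamin B3. Each dose had 3 Affymetrix HG-U133 Plus 2.0 arrays, numbered as batches 1 to 3, so 9 arrays were compared. The deposited log2 values had array medians between 5.67 and 5.71, and 27307 probe sets, which named 13060 genes, were tested. Within a dose, arrays correlated at 0.995 to 0.997 across these probe sets. The mean correlation was 0.967 between 0 and 10 mM, 0.947 between 0 and 5 mM, and 0.892 between 5 and 10 mM. Nothing in the descriptions states that the arrays of a dose came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays, 3 per dose, limits the precision.

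The first comparison asked which transcripts differed between 10 mM isonicotinamide and no isonicotinamide. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose most among the named genes, from 8.30 ± 0.05 to 10.74 ± 0.05 (SD, n = 3, log2), a change of 2.45 with a standard error of 0.05. ACTA2, smooth muscle actin, rose by 1.73 and ARHGDIA by 1.67. The histone genes H2AC6 (1.62), H2BC12 (1.53) and H2BC5 (1.42) rose, as did the stress gene GADD45B (1.53) and the lysosomal ion channel gene MCOLN1 (1.40). CLPTM1 (1.59), PRMT2 (1.56) and PRR14 (1.44) also rose. The RNA-binding protein gene HNRNPD fell by 2.19 on the log2 scale and the nuclear import receptor gene KPNB1 fell by 2.03. The BMP antagonist gene NOG fell by 1.81, ID2, an inhibitor of DNA-binding proteins and a BMP target, fell by 1.81, and SMAD9, a BMP signal transducer, fell by 1.79. The tRNA export receptor gene XPOT had a change of -1.80, the axon guidance gene SLIT2 of -1.76 and the transcriptional corepressor subunit gene TBL1X of -1.76. POGK (-1.84), CKAP4 (-1.79), KCTD12 (-1.75) and FAM20B (-1.75) also fell.

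Across the 27307 probe sets, 6985 rose and 9866 fell at 10 mM (limma, Benjamini-Hochberg adjusted p below 0.05), and 784 and 2801 of these changed by at least 1.5-fold. Of the 16851 called probe sets, 16524 had the same sign of difference in all 3 batches. The genes picked by the naming rule had standard errors between 0.03 and 0.09, and their adjusted p in limma was at most 1.93e-14. The share that rose was 41.5% as deposited and 56.0% with each array scaled to a common median (10151 rose and 7986 fell), so the balance of directions rests on the scaling. The common median, here and below, is that of the tested probe sets and not of all probe sets on the array. This scaling moved the median change of the tested probe sets from -0.02 to 0.07. Other kept probe sets of HNRNPD and KPNB1 rose, by 0.63 and 0.12 (limma adjusted p = 4.44e-07 and 0.0315), against the fall of the named probe sets. Of the 23 genes named for this comparison 17 had several kept probe sets, and for 7 the brightest gave under 50% of the change printed: ARHGDIA (0.66), PRMT2 (0.41), PRR14 (0.19), KPNB1 (-0.97), POGK (-0.18), CKAP4 (-0.54) and TBL1X (-0.78). For 2 genes some probe sets did not pass: PRMT2 (-0.03 and -0.07, limma adjusted p = 0.697 and 0.411) and GADD45B (0.13, limma adjusted p = 0.277).

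**Figure D1:**
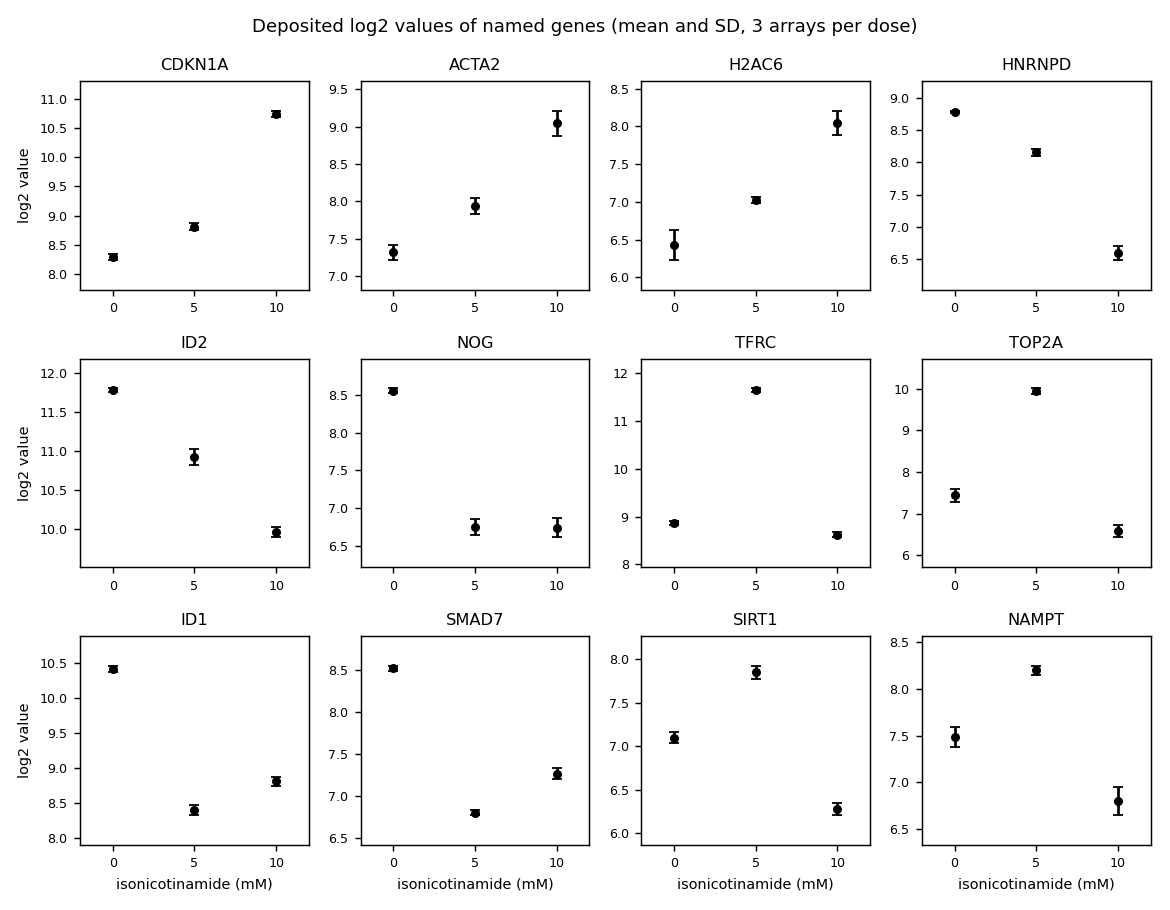
Deposited log2 values (vertical axis) of 12 named genes at 0, 5 and 10 mM isonicotinamide (horizontal axis), where points are means and bars are SDs of 3 arrays. CDKN1A is at 8.30, 8.81 and 10.74, and TFRC at 8.87, 11.65 and 8.62.

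Among the 26 gene lists fixed before the data were examined, 7 were past the threshold at 10 mM. All 6 measured histone genes with polyadenylated transcripts rose, with a median change of 0.88 (camera adjusted p = 9.98e-05, and adjusted p = 0.108 with an estimated correlation), including H2BC12 at 1.53, H2AC6 at 1.62 and H1-2 at 0.73. Of 16 autophagy and lysosome genes 11 rose and 1 fell (camera adjusted p = 0.00416, and adjusted p = 0.108 with an estimated correlation): MCOLN1 rose by 1.40 and the autophagosome protein gene MAP1LC3B by 0.40, whereas GLA, encoding a lysosomal galactosidase, fell by 0.67. At 5 mM this list went the other way, with 12 fallen, 2 risen and a median of -0.27 against 0.28 at 10 mM (camera adjusted p = 0.262 at 5 mM). Of 14 p53 target genes 7 rose and 2 fell, with CDKN1A at 2.45, the death receptor gene TNFRSF10B at 0.71 and TP53I3 at 1.12 (camera adjusted p = 0.0191, and adjusted p = 0.111 with an estimated correlation). MDM2, the p53 ubiquitin ligase gene, fell by 0.63 among them.

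The other 4 lists lay lower at 10 mM. Of 21 hypoxia and glycolysis genes 16 fell and 3 rose, with a median of -0.47 (camera adjusted p = 0.000726, and adjusted p = 0.108 with an estimated correlation). HK2, a hexokinase gene, changed by -1.17, PDK1, which encodes an inhibitor of pyruvate dehydrogenase, by -1.47, BNIP3 by -0.81 and LDHA by -0.60. Of 23 ATF4 and amino acid response genes 17 fell and 4 rose, including DDIT4 at -1.37, the asparagine synthetase gene ASNS at -1.15 and the glycyl-tRNA synthetase gene GARS1 at -1.03 (camera adjusted p = 0.00359, and adjusted p = 0.108 with an estimated correlation). Of 11 heat shock genes 9 fell and 2 rose, with HSP90AA1 at -0.99, HSPD1 at -0.80 and HSP90AB1 at -0.57, whereas BAG3 rose by 0.67 (camera adjusted p = 0.0293, and adjusted p = 0.128 with an estimated correlation). The heat shock list had a median of -0.48 at 10 mM and of 0.54 at 5 mM, where 6 rose and 5 fell (camera adjusted p = 0.185). Of 16 ribosome biogenesis genes 9 fell and 2 rose, among them NCL at -0.94, MYC at -0.86 and NOLC1 at -0.38 (camera adjusted p = 0.047, and adjusted p = 0.308 with an estimated correlation). Adjusted over the list alone, 10 ribosome biogenesis genes fell and 12 autophagy genes rose, and the other 5 lists kept the counts given. The ribosome biogenesis call ended under quantile normalization (adjusted p = 0.0656), with arrays scaled to a common median (0.0571), and without the 0 mM array of batch 1 (0.0506) or the 10 mM array of batch 2 (0.051), all by camera. With the batch number as a block, 3 further lists passed in camera: matrix and TGF-beta or YAP targets, methionine cycle genes, and fatty acid oxidation genes, each with an adjusted p of 0.0469. At 10 mM 26 lists passed with fry, and 12 with camera without the filter on dim probe sets.

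The control probe sets also differed between these doses. The log2 ratio of the 3' to the 5' probe set of ACTB, a measure of RNA and labelling quality, was 0.76 ± 0.06 at 10 mM and 1.06 ± 0.01 at 0 mM (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays allow). The same ratio for GAPDH was 0.32 ± 0.02 and 0.34 ± 0.03 (exact permutation p = 0.5). Of the fibroblast markers, which stand for another cell type, ACTA2 (1.73) and COL1A2 (0.30) rose and the other 3 of 5 did not pass, with COL1A1 at 0.13 (camera adjusted p = 0.079 for the list). Only 2 blood cell markers were among the tested genes, so that list was not tested.

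The second comparison asked the same of 5 mM. TFRC, the transferrin receptor gene, rose most, from 8.87 ± 0.04 to 11.65 ± 0.03 (SD, n = 3, log2), a change of 2.78 with a standard error of 0.04. TPR, a nuclear pore protein gene, rose by 2.49, the DNA topoisomerase gene TOP2A by 2.49, the nuclear export factor gene CSE1L by 2.48, and THOC2, of the mRNA export complex, by 2.36. CEP350 (2.21), BBX (2.18), QSER1 (2.14), the deubiquitinase gene USP9X (2.14), the translation factor gene EIF1AX (2.14), the cohesin subunit gene STAG2 (2.13) and ZBTB10 (2.13) also rose. The genes that fell included several targets or regulators of BMP and TGF-beta signalling: ID1 fell by 2.02, NOG fell by 1.80 and the inhibitory SMAD gene SMAD7 fell by 1.72. CYP26A1, which encodes a retinoic acid hydroxylase, fell by 1.94, the lysyl oxidase gene LOX fell by 1.69, and the galanin gene GAL fell by 1.59. ANKRD37 (-1.50), GPX3 (-1.43), UCP2 (-1.40), the heme oxygenase gene HMOX1 (-1.40), IFITM2 (-1.36) and DDIT4 (-1.31) completed the 12 that fell.

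At 5 mM 7654 probe sets rose and 11112 fell (limma, Benjamini-Hochberg adjusted p below 0.05), and 3886 and 1157 of these changed by at least 1.5-fold. Of the 18766 called probe sets, 18568 had the same sign in all 3 batches, and the 24 named genes had standard errors between 0.04 and 0.09. With arrays scaled to a common median, 6432 rose and 15837 fell, a share of 28.9% against 40.8% as deposited, and that scaling moved the median change of all probe sets from -0.11 to -0.22. Other probe sets of TFRC changed by 2.78, 0.86 and -0.17, and those of ZBTB10 by 1.30, 1.16 and -0.10, of which the last for each gene did not pass.

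Of the 26 lists, 6 were past the threshold at 5 mM. Of 21 hypoxia and glycolysis genes 18 fell and 3 rose, with a median of -0.44 (camera adjusted p = 0.00159, and adjusted p = 0.124 with an estimated correlation). HK2 changed by -0.33, BNIP3 by -0.42 and LDHA by -0.14, whereas PDK1 rose by 0.15. Of 12 matrix and TGF-beta or YAP targets 10 fell and 0 rose, including ID2 at -0.85, ID1 at -2.02, SMAD7 at -1.72 and ID3 at -1.29 (camera adjusted p = 0.00314, and adjusted p = 0.124 with an estimated correlation). The YAP target CCN1 changed by -0.64. Of 7 metallothionein genes, which encode metal-binding proteins, 6 fell, with MT1X at -1.10, MT2A at -0.82 and MT1F at -0.68 (camera adjusted p = 0.0253, and adjusted p = 0.268 with an estimated correlation).

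The 3 lists that lay higher at 5 mM were mixed. Of 14 p53 targets 8 rose and 3 fell, with CDKN1A at 0.51 and MDM2 at 0.48 while TP53I3 fell by 0.37 (camera adjusted p = 0.0253, and adjusted p = 0.178 with an estimated correlation). Of 23 mitosis genes 11 rose and 10 fell: TOP2A rose by 2.49 and BUB1 by 0.61, whereas PLK1 fell by 0.60 (camera adjusted p = 0.0326, and adjusted p = 0.221 with an estimated correlation). Of 18 cholesterol genes 9 rose and 5 fell, with INSIG1, a regulator of cholesterol synthesis, at 0.38 and the squalene epoxidase gene SQLE at 0.92 (camera adjusted p = 0.0326, and adjusted p = 0.309 with an estimated correlation). The medians of the mitosis and cholesterol lists, 0.05 and 0.11, became -0.06 and -0.01 with arrays scaled to a common median. All 3 calls ended when every kept probe set of a gene was averaged, with an adjusted p of 0.0759 for each by camera. Adjusted over the list alone, the counts for all 6 lists were the same, and 22 lists passed with fry at this dose.

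The ACTB ratio at 5 mM was 1.22 ± 0.04, against 1.06 ± 0.01 at 0 mM, and the GAPDH ratio was 0.42 ± 0.03 against 0.34 ± 0.03 (log2, SD, n = 3; exact permutation p = 0.1 for each). Spike-in transcripts added with a poly-A tail (Dap, Lys, Phe, Thr and Trpn) had a mean log2 value of 7.11 ± 0.01 at 5 mM, 7.44 ± 0.07 at 0 mM and 7.58 ± 0.05 at 10 mM. The hybridization spike-ins lay at 10.30 ± 0.07, 10.32 ± 0.03 and 10.36 ± 0.12 (exact permutation p = 0.7 for 5 against 0 mM). Of the 5 fibroblast markers 1 rose and 2 fell at 5 mM (camera adjusted p = 0.98), with ACTA2 at 0.62.

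**Figure D2:**
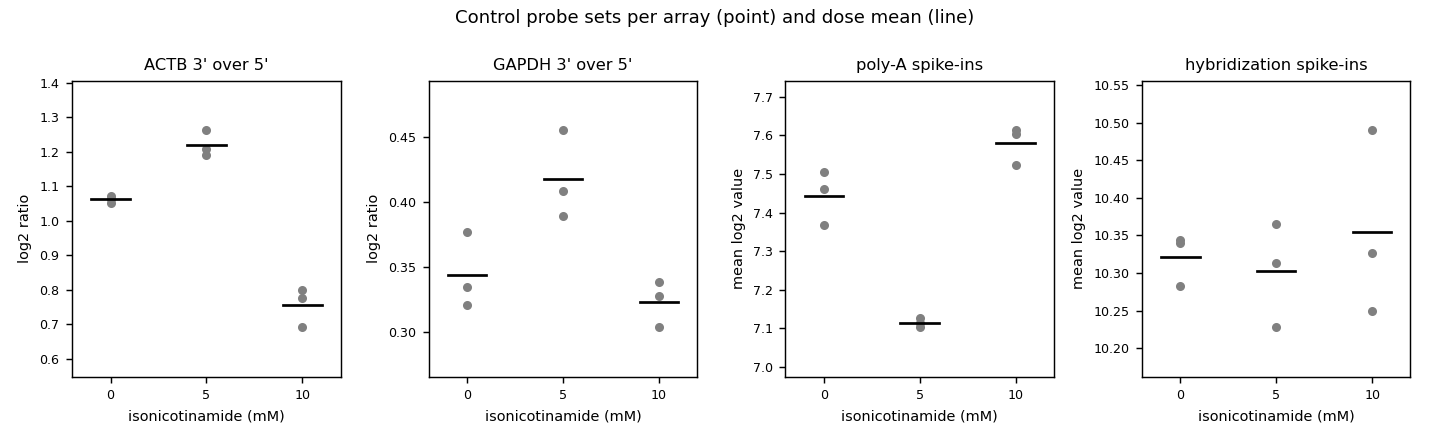
Control probe sets on each of the 9 arrays (grey points) and their dose means (black lines) against isonicotinamide dose in mM. The vertical axes, which do not start at 0, give log2 ratios of the 3' to the 5' probe set for ACTB and GAPDH and mean log2 values for the spike-ins, and the ACTB means are 1.06, 1.22 and 0.76 at 0, 5 and 10 mM.

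Genes of NAD metabolism and the enzymes that consume NAD were followed because nicotinamide, the isomer, is an NAD precursor and an inhibitor of such enzymes. Whether isonicotinamide shares these properties was not examined. SIRT1, the NAD-dependent deacetylase gene, changed by -0.82 at 10 mM and by 0.75 at 5 mM. NAMPT, the rate-limiting enzyme of NAD salvage, changed by -0.68 and 0.71 (limma adjusted p at most 8.99e-09 for both genes and doses). In all 4949 probe sets rose at 5 mM and fell at 10 mM, so this pattern is not particular to NAD genes. Technical explanations for it stay open, as described below. PARP1 had values of -0.04 at both doses (limma adjusted p = 0.24 and 0.258), and NNMT was not among the tested genes. Of 12 NAD synthesis and breakdown genes 4 rose and 1 fell at 10 mM, and 2 rose and 5 fell at 5 mM (camera adjusted p = 0.248 and 0.691). NAPRT, of the nicotinic acid route, rose by 0.61 at 10 mM and fell by 0.41 at 5 mM, and NADSYN1 rose by 0.56 at 10 mM. Of 14 sirtuin and PARP genes 4 rose and 5 fell at 10 mM, and 5 rose and 7 fell at 5 mM (camera adjusted p = 0.815 and 0.691). PARP2 fell by 0.67 at 10 mM, SIRT7 changed by 0.49 and -0.41 at 10 and 5 mM, and SIRT6 by 0.37 and -0.33. At 5 mM this list had a median of -0.14 and a mean of 0.13.

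**Figure D3:**
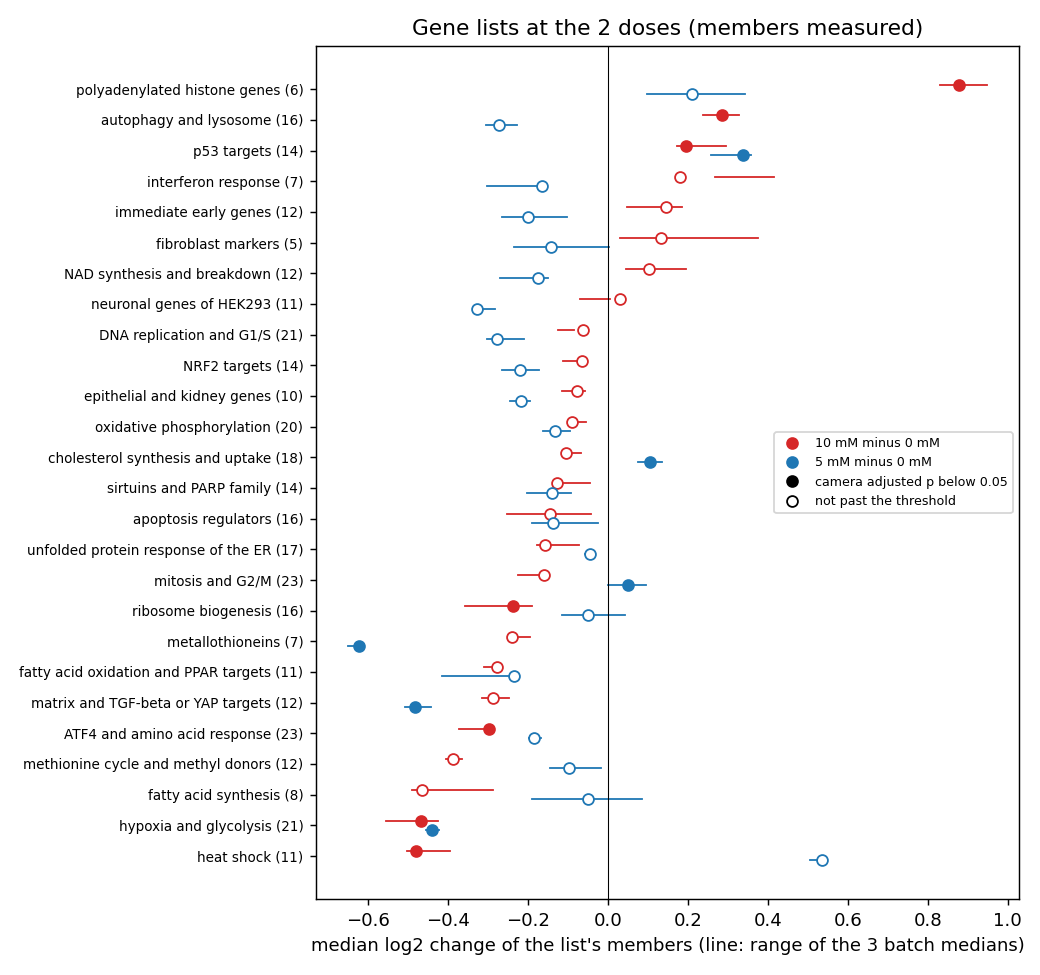
Median log2 change of the measured members of 26 gene lists at 10 mM (red) and 5 mM (blue) against 0 mM, with lines for the range of the 3 batch medians, which need not hold the pooled median, and filled points for a camera adjusted p below 0.05. The hypoxia and glycolysis list lies at -0.47 and -0.44, and the 5 mM medians of the mitosis and cholesterol lists turn to -0.06 and -0.01 with arrays scaled to a common median.

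The third comparison set 10 mM against 5 mM. The nuclear import receptor gene TNPO1 was lower at 10 mM by a log2 difference of -3.49, TPR by -3.45, TOP2A by -3.35, the microRNA-processing enzyme gene DICER1 by -3.18 and EPRS1, a tRNA synthetase gene, by -3.12. ARHGDIA was higher at 10 mM by 2.01, CDKN1A by 1.93, the glutathione peroxidase gene GPX3 by 1.82 and MCOLN1 by 1.77. The brightest ARHGDIA probe set gave 0.94, and the smallest differences among the other probe sets of TNPO1, TPR, TOP2A, DICER1 and EPRS1 were -1.63, -2.33, -1.80, -1.87 and -1.81. In all, 13017 probe sets were higher and 9709 lower at 10 mM (limma, Benjamini-Hochberg adjusted p below 0.05), and 3005 and 6224 of them by at least 1.5-fold. With arrays scaled to a common median 16571 were higher and 7987 lower, a share of 67.5% against 57.3% as deposited. The ACTB ratio differed by -0.46 and the poly-A spike-ins by 0.47 between these doses (log2, exact permutation p = 0.1 for each).

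Many probe sets changed in opposite directions at the 2 doses. TPR, SIRT1 and NAMPT rose at 5 mM and fell at 10 mM, as did the named probe sets of TFRC and TOP2A, while GPX3, ARHGDIA and MCOLN1 went the other way. At 10 mM another TOP2A probe set gave -0.04 (limma adjusted p = 0.613) and a dim TFRC probe set rose by 0.25 (limma adjusted p = 0.0445). Across probe sets the changes at 5 and 10 mM had a Pearson correlation of -0.297, and -0.281, -0.23 and -0.264 within batches 1, 2 and 3, where probe sets are not independent replicates. Unchanged groups simulated against the same 0 mM arrays gave 0.501. The covariance was -0.0587 against a simulated 0.00296. Opposite signs, whether or not the probe sets passed, were found for 66.1%. Among probe sets that passed at both doses, 4949 rose at 5 mM and fell at 10 mM, where independent lists would share 2765, and 3695 fell at 5 mM and rose at 10 mM, against 2842. The number of probe sets that fell at 5 mM and rose at 10 mM was 7554 with arrays scaled to a common median and 2446 without batch 1.

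Some genes fell at both doses. NOG (-1.80 at 5 mM and -1.81 at 10 mM), ID1 (-2.02 and -1.61), CYP26A1 (-1.94 and -1.36), DDIT4 (-1.31 and -1.37) and SMAD7 (-1.72 and -1.26) were among them. The histone gene H2BC12 (0.86 and 1.53), ACTA2 (0.62 and 1.73) and CDKN1A (0.51 and 2.45) rose at both. In all 3214 probe sets fell at both doses (4015 for independent lists) and 673 rose at both (1958). Among changes of at least 1.5-fold 239 fell at both doses, where independent lists would share 119, and 23 rose at both, against 112. Of the opposite changes of at least 1.5-fold, 916 rose at 5 mM and fell at 10 mM, against 399, but only 9 fell at 5 mM and rose at 10 mM, against 33.2, so the excess of that class among all calls did not hold among larger changes. With the 0 mM arrays split so that the doses shared none, the correlation lay between -0.328 and -0.284 over 6 arrangements. The probe sets that rose at both doses then numbered 440 to 507, and those that fell at both 2491 to 2688, of which 225 to 244 by at least 1.5-fold (1.73 to 2.03 times the number for independent lists).

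**Figure D4:**
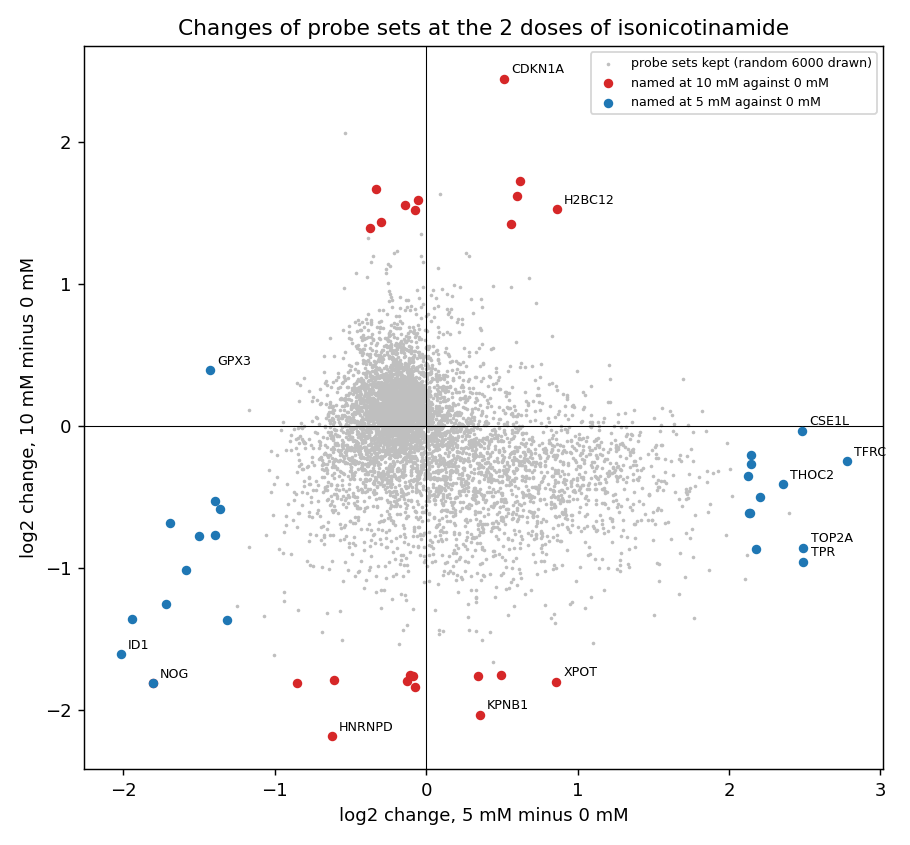
Log2 change at 5 mM (horizontal axis) against log2 change at 10 mM (vertical axis), both relative to 0 mM, for a random 6000 probe sets (grey) and the named genes of each comparison (red and blue). TFRC lies at 2.78 and -0.25, CDKN1A at 0.51 and 2.45, and NOG at -1.80 and -1.81.

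A linear dose trend was fitted last. H2BC12 had a slope of 0.15 log2 units per mM (limma adjusted p = 8.06e-06) and CDKN1A one of 0.24 per mM (limma adjusted p = 0.00137), a test of the slope and not of a straight line: CDKN1A rose by 0.51 at 5 mM and by 2.45 at 10 mM. In all 588 probe sets had a rising and 1722 a falling slope (limma, Benjamini-Hochberg adjusted p below 0.05). With equal numbers of arrays at evenly spaced doses, the slope depends only on the 10 and 0 mM means. The 5 mM arrays enter its error alone, so these counts restate the 10 against 0 mM comparison with a different error. NOG passed (limma adjusted p = 0.0162) with changes of -1.80 at 5 mM and -1.81 at 10 mM. The number of probe sets with a linear dose trend was 2310, but 614 with the batch number of the titles as a block, 413 with that of the source names, 1171 with arrays scaled to a common median and 1493 without the filter on dim probe sets. It was 1150, 1117 and 1053 without the 0 mM arrays of batches 1, 2 and 3, 931, 890 and 984 without the 10 mM arrays, and 4, 4 and 10 without batches 1, 2 and 3.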

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

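The tests of explanations in this part were chosen after the main results had been seen, and the final AT-rich list used for length and base composition, and the bound for exchanged labels after the values they test had been seen. Signals in the control probe sets, which no comparison used, differed between the doses. The mean log2 value of 15 poly-A spike-in probe sets (Dap, Lys, Phe, Thr and Trpn) was 0.136 higher at 10 mM than at 0 mM, and that of the 12 r2-Bs probe sets 0.15 higher. At 5 mM they were lower than at 0 mM by differences of -0.33 and -0.44, so 20 of 27 such probe sets ran in the order 5, 0, 10 mM.

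That order is also the order of the arrays themselves, since changes at 5 and 10 mM opposed each other (r = -0.297). Scaling between arrays is argued against as the source of this correlation, which was -0.325 after quantile normalization and which a shift of whole arrays cannot move. That does not cover the counts of opposite calls, since calls in each direction did move with scaling. The share of calls that rose at 10 mM went from 41.5% to 56.0% with a common median. Transcript length alone stays open: 20 mRNAs chosen as long and GC-rich from general knowledge had a median change at 5 mM of 0.0632 relative to all genes (95% bootstrap interval -0.06 to 0.21), and 13 chosen as long and AT-rich one of 1.43. The bound written for this, a GC-rich median at or below 0, was not met. Base composition stays open too: the lists differed by 1.37 at 5 mM and by -0.36 at 10 mM (permutation p = 8e-05 and 0.025). That permutation moved genes between the lists, and the bootstrap resampled genes. Both treat genes as independent and do not measure the spread between arrays. Camera with an estimated correlation gave the AT-rich list an unadjusted p of 0.00361 at 5 mM and 0.0852 at 10 mM. An earlier version of the AT-rich list held CENPE, whose value had already been seen, and gave medians of 1.45 at 5 mM and -0.32 at 10 mM over 14 measured genes. Neither length nor composition was measured, and the lists also differ in function. They differ in brightness as well: at 0 mM the AT-rich members lay between 5.39 and 7.10, the GC-rich ones between 6.14 and 12.6 (log2). Probe sets were kept by their mean over all arrays, at least 5.71, so a rise at 5 mM helped dim members to be kept. Of 19 AT-rich mRNAs listed 13 were measured, and VPS13C (5.39) and VPS13B (5.61) lay below that cutoff at 0 mM. The difference between the lists therefore does not isolate base composition.

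RNA quality or labelling that differs between the dose groups cannot be told apart from dose, because each dose is a single group: within doses, an array's place between 10 and 5 mM correlated with its ACTB ratio at r = 0.429 (exact permutation p = 0.37) and Spearman's rho = 0.283 (exact permutation p = 0.606) over 9 arrays, and at 0.337 without the 2 arrays farthest from the median. An exchange of the 0 and 5 mM labels cannot be told apart either, since any group that lies between the other groups gives a high correlation when an outer group is the reference (0.858 here). A response to isonicotinamide that differs in direction between the doses was not tested.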

How the results depend on the processing

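Counts for probe sets that changed at both doses and the ACTB ratio, and fits with the 0 mM arrays split between the doses, were alternatives chosen after seeing the data. With that split, probe sets that rose at both doses numbered 440 with the batch 3 array alone for 10 mM, and 440 to 507 in all, and the 9 that fell at 5 mM and rose at 10 mM by at least 1.5-fold became 9 to 16; the cause was not tested. The pseudocount alternatives were not run, because the values were already on a log scale. Of 1343 values for named genes under alternatives, 1340 kept direction and side of the threshold; PARP1 at 10 mM turned to 0.0516 under quantile normalization and 0.0423 with a common median, without passing, and at 5 mM it passed with a common median (-0.15). The common median moved every change by the same amount, 0.0863 at 10 mM and -0.114 at 5 mM, which gives the PARP1 values under that scaling. The cause of the PARP1 value under quantile normalization was not tested. With the batch block the counts were 16847 for probe sets changed at 10 mM against 0 mM, 18736 for probe sets changed at 5 mM against 0 mM and 22709 for probe sets changed at 10 mM against 5 mM.

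Requiring 1.5-fold, a stricter rule by construction, left 3585, 5043 and 9229 probe sets in these comparisons, 23 that rose and 239 that fell at both doses, 916 that rose at 5 mM and fell at 10 mM, and 9 that did the reverse. With fewer tested (upper 30%), the number of probe sets changed at 10 mM against 5 mM was 14382, by construction. The number of probe sets with a linear dose trend was 614 with the batch block, 413 with the block by source names, 1171 with a common median and 1493 without a filter. With a common median the number of probe sets that fell at 5 mM and rose at 10 mM was 7554. That scaling moved every change up at 10 mM and down at 5 mM, which raises this class by construction. The cause was not tested for the dose trend counts.

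No list passed with an estimated correlation (0 at each dose), 26 and 22 passed with fry at 10 and 5 mM, 12 passed at 10 mM without a filter, and 3 passed at 5 mM with probe sets averaged. Leaving out arrays or batches gave 14676 to 16678 probe sets for 10 against 0 mM, 16479 to 19087 for 5 against 0 mM, 20984 to 22664 for 10 against 5 mM, and 4 to 2418 for the dose trend, where the lowest counts, 4, 4 and 10, came without batches 1, 2 and 3. It gave 500 to 663 that rose and 2703 to 3190 that fell at both doses, 4243 to 4963 that rose at 5 mM and fell at 10 mM, and 2446 (without batch 1) to 3759 that did the reverse. Lists numbered 6 to 10 at 10 mM and 6 to 6 at 5 mM. The correlation between doses lay between -0.293 and -0.283 without a 0 mM array, -0.290 without a filter and -0.325 after quantile normalization. The ACTB ratio difference between 10 and 0 mM lay between -0.328 and -0.275.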

Other observations

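The tests of other BMP, hypoxia and deacetylase inhibitor genes were chosen after the main results had been seen, and the bound and final list of the last after its own value had been seen. Some further single genes changed, while the fixed lists of apoptosis regulators, neuronal genes and immediate early genes passed at neither dose. Among apoptosis regulators BAX rose by 0.99 at 10 mM, while PMAIP1 changed by -1.15 at 10 mM and 0.97 at 5 mM. Of the neuronal genes that HEK293 expresses, NEFM fell at both doses (-1.72 at 10 mM and -0.66 at 5 mM). The immediate early gene JUND rose at both doses, by 1.04 at 10 mM and 0.68 at 5 mM. Single probe sets of the ribosomal protein genes RPS15A (1.14 and 0.77) and RPL31 (0.87 and 0.73) also rose at both. Each was picked for its large change, and other probe sets of these genes are not given. SLC2A3, a glucose transporter gene that belongs to the fixed hypoxia and glycolysis list, changed by -1.27 and -1.25. The transcription factor gene BHLHE40 changed by -1.47 and -1.23. These genes were chosen after their values were seen.

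A lower BMP response at both doses is a hypothesis drawn from NOG, ID1, ID2 and SMAD7. It was tested on 16 other BMP target genes listed before their values were seen, of which 11 were measured. Of these 9 fell at both doses, including BAMBI (-0.82 at 10 mM and -0.96 at 5 mM), MSX2 (-0.90 and -1.01), GATA3 (-0.63 and -0.91) and ID4 (-1.44 and -0.56), and ATOH8 rose by 0.28 at 10 mM. The larger camera p of both doses was 6.35e-05, and with an estimated correlation the p was 0.0315 at 10 mM and 0.0285 at 5 mM. These p-values are unadjusted, unlike the adjusted p given for the fixed lists. Unadjusted, camera with an estimated correlation gave the fixed hypoxia and glycolysis list 0.00489 at 10 mM and 0.00502 at 5 mM. That list did not pass once adjusted. The falls of these BMP targets are what a lower BMP response would give, but they do not show which step changed. They also do not show whether the 0 mM arrays, shared by both comparisons, stand apart for another reason.

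A lower hypoxia response was tested in the same way on 20 measured hypoxia target genes outside the fixed list. Their median relative to all genes was -0.12 at 10 mM and 0.06 at 5 mM, and the larger camera p was 0.926. MXI1 fell at both doses (-1.04 and -0.20), whereas PLOD2 fell at 10 mM (-0.78) and rose at 5 mM (1.13). The members went both ways, so the test did not extend the fall of the fixed hypoxia and glycolysis list to other targets.

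The rise of CDKN1A and histone genes at 10 mM suggested a comparison with histone deacetylase inhibitors, which are known to raise these genes. Of 8 other measured genes known to rise under such inhibitors 7 rose at 10 mM, with a median of 0.33 relative to all genes (95% bootstrap interval over genes 0.18 to 0.67). The camera p was 0.00363, and 0.0237 with an estimated correlation. The camera p-values of this list are unadjusted, unlike those of the fixed lists. CLU rose by 0.55, CRIP2 by 0.68 and TUBB6 by 0.67, while GLRX fell by 0.20. At 5 mM the median was -0.19 and 6 of the 8 fell, but the list did not pass (95% bootstrap interval -0.36 to 0.01; camera p = 0.0598, and p = 0.0994 with an estimated correlation). The medians of this list, the autophagy and lysosome list and the heat shock list had opposite signs at the 2 doses, though none passed at 5 mM, and the technical explanations left open for the opposite changes may apply to them.

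The real division of the 6 arrays gave 16851 calls for 10 against 0 mM, 18766 for 5 against 0 mM and 22726 for 10 against 5 mM, and the highest of the other divisions gave 0 in each. It gave 7 and 6 gene lists at 10 and 5 mM, and the highest others gave 4 and 3. The real division was the 1 with most calls among 10 each time, and 10 divisions are too few for a share under 0.05. Every other division mixes arrays of both doses, so the difference between doses enters its spread. The 0 calls there were to be foreseen and do not measure chance. Of the 10 divisions 4 divide each batch as the real one does; among these the highest others gave 0 calls in each comparison, and 0 and 3 lists.

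For the dose trend, 4 of 100 drawn assignments of the doses to all arrays, the real one included, gave at least the 2310 calls observed, and the highest other gave 14004. With the doses assigned within batches, a test chosen after the results had been seen, 11 of 100 did, the highest other giving 19545. With the batch block as well, 7 of 100 gave at least the 614 probe sets with a linear dose trend of that fit, the highest other giving 18435. Each other assignment within batches that reached these counts kept all 5 mM or all 10 mM arrays at a single dose. Such assignments retain differences between the dose groups, so the 11 and 7 of 100 neither exclude nor measure chance for the trend. The highest count came with the 0 and 5 mM arrays exchanged, which points to a structure of the arrays, in the order 5, 0 and 10 mM, that a line in dose does not follow.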
